A study of Mus musculus with 3 samples.

How the data were processed

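Single cells of 3 sorted bone marrow populations, LMPP, CLP and pro-B, were profiled per the labels with the 10x Chromium 3-prime v2 chemistry, 1 library per population. The deposited files hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger on mm10, per the submitters' processing notes. The version of Cell Ranger, its gene annotation and the rule by which barcodes were called cells are not given in the sources used here. The labels also describe cultured iLS cells, which were not analysed here. Immunoglobulin heavy and light chain genes were not analysed here. With 1 library per population, any difference between droplet runs is confounded with the population.

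Each library was named from its label alone. Of 599, 979 and 1123 deposited barcodes (LMPP, CLP, pro-B), those with 500 or more genes and at most 10% mitochondrial UMIs were kept. This left out 20, 31 and 16 barcodes for mitochondrial UMIs and 0, 0 and 1 for few genes, and kept 579, 948 and 1106 cells. Before any filter the libraries held 4049034, 6025391 and 7410404 UMIs. The libraries shared 3 (CLP and LMPP), 2 (pro-B and CLP) and 1 (pro-B and LMPP) barcode sequences. Possible doublets were scored per library with scrublet as run in scanpy, which called 30, 14 and 2 cells. In pro-B the calls may be a lower limit, because doublets of like cells resemble single cells. In LMPP 5.18% of cells were called, against an expected rate set to 1%. Of the 30 calls there 12 lay in 1 cluster of 91 cells, so some may be false. All called cells were kept in the main values and left out in an alternative.

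UMI counts were summed over the kept cells of a library and divided by the library total to give CPM. At these depths 50 CPM is 201, 298 and 368 UMIs, and the floor of 3 UMIs is 0.75, 0.50 and 0.41 CPM in LMPP, CLP and pro-B. Ratios of CPM were computed for CLP over LMPP, pro-B over CLP and pro-B over LMPP, with exact conditional (Clopper-Pearson) intervals of the ratio of 2 Poisson counts and exact Poisson intervals of each level. Where a library had no UMI it was set to 3 UMIs and the fold given as a bound. No test was made and no p-value computed. A gene counted as different when its ratio was 4-fold or more and it had 50 CPM or more in the higher library. Relative to the library total, scaling by the total without mitochondrial and ribosomal genes moves every log2 ratio by −0.03 for CLP over LMPP, −0.31 for pro-B over CLP and −0.34 for pro-B over LMPP, and median-of-ratios scaling by −0.01, 0.10 and 0.10. The median log2 ratio of genes with 50 CPM or more was −0.01, 0.34 and 0.36.

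The filters, the comparisons, 20 gene lists, 16 lists of cell type markers, the genes whose shares are given and most alternatives were chosen before the data were examined. The rule for named genes took, for CLP over LMPP and for pro-B over CLP, the 10 highest and the 10 lowest ratios among genes with 50 CPM or more in the higher library, leaving out sort markers, immunoglobulin, mitochondrial, Rpl and Rps genes and unnamed gene models. It added the sort markers, all regulators of B lymphopoiesis, the genes whose shares are given and up to 4 members of every other list with the highest CPM, 117 genes in all, some of which are not reported here. Genes named for leading a cluster, and the other genes said to be, fall outside the rule. A list's value is the median log2 ratio of its members with 10 or more UMIs over both libraries, with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. Its interval comes from redrawing each count as a Poisson count.

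For shares of cells, every cell was thinned without replacement to 2000 UMIs. Shallower cells were left out, 6 in LMPP, 40 in CLP and 36 in pro-B. Shares have exact Clopper-Pearson 95% intervals. Co-detection is the share of thinned cells with both of 2 genes, set beside the product of the single shares. Cell cycle shares count thinned cells with 3 or more UMIs of a list. Each library was clustered on its own from counts scaled to 10000 per cell and logged, with 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.5. Clusters were named from the fixed markers only. Gene positions were taken from GENCODE M21 (GRCm38), where all 117 named genes were matched by Ensembl ID.

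Computations ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. The steps were tested on simulated library sums of 15922 genes, drawn as Poisson counts from 1 shared profile, with 200 genes changed per comparison. For CLP over LMPP, 0 of 67 genes changed 2-fold, 38 of 67 changed 4-fold and 66 of 66 changed 8-fold were called. For pro-B over CLP and pro-B over LMPP the calls at 4-fold were 39 and 33 of 67, with the same counts at the other sizes. A true 4-fold change sits on the threshold, so about as many fall on either side. No unchanged gene was called, and the intervals held the true ratio for 95.8%, 95.7% and 95.7% of genes. Since the simulated counts held counting error only, this outcome was largely built in and checks the computation. It does not show how calls and intervals behave where a few cells hold most UMIs of a gene. Of 20 unchanged lists 0 lay outside the middle 95% in each comparison. The alternatives covered the scaling, the weight of cells, the cell filter, doublets, deep cells, count minimums, the fold, thinning, detection thresholds and clustering settings.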

Results

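The data cover 3 populations of blood cell progenitors sorted from the bone marrow of C57BL/6J mice, each profiled as 1 library of single cells in droplets, with counts of unique molecular identifiers (UMIs, tags that mark single captured transcripts) for 27998 genes. Lymphoid-primed multipotent progenitors (LMPP) were sorted as cKit+ Sca1+ Flt3+ cells without IL7Ra and B220. Common lymphoid progenitors (CLP) were sorted as cKit+ Sca1+ Flt3+/- IL7Ra+ cells without B220, and pro-B cells as cKit+ IL7Ra+ B220+ cells without Sca1 and Flt3. After filtering, 579 LMPP, 948 CLP and 1106 pro-B cells were kept, with 4014657, 5967352 and 7367156 UMIs in all. The median cell held 6789 UMIs and 2081 genes in LMPP, 6258.5 UMIs and 1953 genes in CLP, and 5687.5 UMIs and 2027 genes in pro-B. Ribosomal protein genes took 43.5% of UMIs in LMPP, 41.9% in CLP and 29.6% in pro-B, and mitochondrially encoded genes took 2.67%, 3.10% and 2.09%. With 1 library per population there was no replicate, so no test was made and no difference has a replicate check. Levels are summed counts scaled to 1000000 UMIs per library (CPM, counts per 1000000), and all intervals are 95% intervals that cover counting error only.

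The genes behind the sort gates served as a check of the labels and are no finding, since the cells were sorted on their proteins. Il7r, the gene of IL7Ra, stood at 3.74 CPM in LMPP against 141 in CLP and 104 in pro-B. Ly6a, which encodes Sca1, stood at 114, 41.1 and 6.11 CPM, Flt3 at 279, 300 and 5.16 CPM, and Kit at 85.2, 28.3 and 7.47 CPM in LMPP, CLP and pro-B. Every gate was cKit+, so Kit cannot tell the labels apart, and its fall is not given by the gates as labelled. The same holds for Ly6a between LMPP and CLP, which were both Sca1+. The median log2 ratio of these 5 genes, Ptprc included, was 0.11 for CLP over LMPP and −1.92 for pro-B over CLP. Ptprc, whose B220 form the gates used, stood at 59.3, 80.3 and 33.4 CPM, but a count per gene does not separate the forms.

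The comparison of CLP with LMPP asks what distinguishes the sorted lymphoid progenitor from its multipotent predecessor. B lineage genes stood far higher in CLP, while stem cell and most myeloid genes stood lower. Ebf1, a transcription factor that specifies the B lineage, was 59.2-fold higher (472 against 7.97 CPM, log2 ratio 5.89, interval 5.39 to 6.44). Cd79a, a signalling chain of the B cell receptor, was 61.7-fold higher (log2 5.95, 4.82 to 7.40), and Rag1, the recombinase that cuts antigen receptor genes, was 29.5-fold higher (log2 4.88, 3.89 to 6.11). Both folds rest on few LMPP cells: Cd79a had 6 UMIs there, 5 of them in 1 cell, and Rag1 had 8 in 5 cells. In the other direction Prtn3, a protease of neutrophil granules, was 38.9-fold lower in CLP (7.71 against 300.0 CPM, log2 −5.28, −5.74 to −4.86), and Hlf, a stem cell transcription factor, was 17.2-fold lower (log2 −4.10, −4.58 to −3.66). Of 2570 genes with 50 CPM or more in either library, 35 were at least 4-fold higher and 23 at least 4-fold lower in CLP, and 92.6% lay within 2-fold.

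The other genes with the highest ratios in CLP were also largely B lineage genes. Vpreb3 and Vpreb2, components of or partners to the surrogate light chain of the pre-B receptor, had log2 ratios of 6.66 (5.11 to 8.95) and 6.41 (4.85 to 8.69), each resting on 3 UMIs in LMPP. Vpreb2 has a close paralog, Vpreb1, and the counting may divide transcripts between them. Mzb1 (26.9-fold), the adaptor Blnk (14.5-fold), Arl5c (11-fold) and the GTPase gene Gimap4 (15.5-fold) followed. Ly6d, a surface protein gene that marks B-biased CLP, was 16.1-fold higher (873 against 54.3 CPM), with 79.4% of its UMIs in LMPP in 5 cells. Without the dendritic-like and innate-like clusters of cells, an alternative chosen after the data were seen, Ly6d was 82-fold and Blnk 23.7-fold higher, and Vpreb3 had a log2 ratio of 8.31 (5.83 to 13.6, from 1 UMI in LMPP). The LMPP cluster left out is led by Ly6d and held 192 of its 218 LMPP UMIs and 15 of the 37 of Blnk. These 2 folds thus rise through the choice of cells. With plasmacytoid dendritic-like cells left out of CLP alone, the log2 ratio of Ly6d fell from 4.01 to 3.34 (3.14 to 3.54). The genes with the lowest ratios included Rab38 (27.1-fold lower), the homeobox gene Nkx2-3 (23.5-fold), Myct1 (14.8-fold), Cd63 (13.6-fold), Mecom (12.2-fold), Ccl9 (11-fold) and the carbonic anhydrase gene Car2 (10.2-fold).

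Gene lists were described by the median log2 ratio of their members and its place among 10000 random lists matched on expression. All 12 regulators of B lymphopoiesis were measured for CLP over LMPP. Of these, 10 were at least 2-fold higher in CLP, with a median of 2.41 (1.94 to 2.73) that lay above every random list. Pax5, which fixes B lineage identity, had no UMI in LMPP and 17.3 CPM in CLP, at least 23.1-fold higher. Foxo1 was 5.95-fold, Ets1 4.84-fold and Bach2 3.18-fold higher, and Pou2af1 at least 10.99-fold, whereas Tcf3 (1.14-fold) and Bcl11a (1.11-fold) differed little. Ikzf3, counted among the 10, had no UMI in LMPP and 26 in CLP, but 24 of these lay in a cluster of 13 NK/innate lymphoid-like cells and the other CLP cells stood at 0.34 CPM (2 UMIs), under the floor of 3 UMIs. Spib, also among the 10, had 4 UMIs in LMPP and 42 in CLP, of which 30 lay in the plasmacytoid dendritic-like cluster. Lef1 had no UMI in LMPP and only 12 in CLP. The count of 10 thus rests in part on cells named for other lineages and on few UMIs. Of 12 genes of the pre-B receptor and B cell surface, 10 were at least 2-fold higher (median 3.54, 3.19 to 4.01), including Vpreb1 (9.24-fold) and Igll1 (48.8-fold from 2 UMIs in LMPP, log2 5.61, 3.73 to 8.67). Few cells carried the Igll1 level of CLP, with 66.2% of its 145 UMIs in 5 cells and 115 in a cluster of 67 early B-like cells. The early lymphoid list had 7 of 11 members at least 2-fold higher and none lower (median 1.59, 1.01 to 2.14), with Dntt, the terminal transferase, 4.45-fold and Satb1 2.01-fold higher. These lists, too, lay above every random list.

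The stem and multipotent list had 15 of 16 members at least 2-fold lower in CLP and none at least 2-fold higher, with a median of −1.85 (−2.11 to −1.74) below every random list. Ifitm1 was 8.85-fold, Lmo2 3.79-fold and Cd34 2.74-fold lower. Of 10 measured myeloid genes 5 were at least 2-fold lower (median −0.93, −1.33 to −0.83, below every random list). Cebpa, a myeloid transcription factor, was 5.44-fold, Lyz2 2.04-fold and Spi1 1.78-fold lower, but Mpo, which encodes myeloperoxidase, had 71.4 CPM in CLP against 74.2 in LMPP (log2 −0.06, −0.27 to 0.16). Of 12 measured T and innate lymphoid genes 8 were at least 2-fold higher (median 1.28, 1.04 to 1.56, above every random list), among them Id2 (3.90-fold) and Lck (2.32-fold). Gata3 was 2.54-fold higher with all cells, but 76 of its 98 UMIs in CLP lay in the 13 NK/innate lymphoid-like cells and the other CLP cells stood at 3.73 CPM against 6.48 in LMPP. Without the dendritic-like and innate-like clusters the log2 ratio of Gata3 was −0.75 (−1.63 to 0.13), Id2 was 2.58-fold higher and the list median was 1.04, still above every random list. Among Notch receptors and targets, 4 genes were measured (median 1.55, percentile 99.92), with Hes1 9.48-fold, Ptcra 4.46-fold, Nrarp 1.93-fold and Notch1 1.76-fold higher. Of the 53 Ptcra UMIs in CLP 81.1% lay in 5 cells. Of 5 dendritic cell genes 3 were at least 2-fold higher (median 1.598, 0.56 to 1.97), with Siglech at 6.91-fold and Irf8 at 3.68-fold. Without those clusters Irf8 was 5.63-fold higher, but the LMPP cluster left out held 307 of its 502 LMPP UMIs. With plasmacytoid dendritic-like cells left out of CLP alone, its log2 ratio fell from 1.88 to 1.18 (1.03 to 1.33). The dendritic median was 0.70 when every cell weighed the same and 0.59 over all members with a UMI.

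Smaller differences were seen in other lists for CLP over LMPP. MHC class II genes had a median of −0.71 (−0.88 to −0.25, percentile 0.1), with Cd74 1.64-fold lower. Glycolysis genes had a median of −0.69 (−0.79 to −0.51, below every random list), with Aldoa 2.496-fold and Pkm 1.63-fold lower. Interferon stimulated genes had a median of −0.83 (−1.10 to −0.37), with Oasl2 3.43-fold and Isg15 2.48-fold lower. Immediate early genes, which cell handling can raise, had a median of −0.53 (−0.80 to −0.44), with Fos 1.90-fold lower. V(D)J recombination genes (median 0.33, percentile 98.7) included Xrcc6 at 4.63-fold higher, but came inside the middle 95% of random lists without the dendritic-like and innate-like clusters (0.16, percentile 90.8) and over members with 1 or more UMIs (0.23, 96.2). E and Id protein genes had a median of 0.59 (percentile 98.9) and G2/M genes of 0.48 (99.9), the latter at −0.11 (37.9) in cells with few cycle UMIs only. S phase genes had a median of 0.22 (98.0) that came inside the middle 95% in 5 alternatives: with equal weight per cell (0.19, percentile 95.3), with all barcodes (0.20, 96.8), without scrublet calls (0.20, 97.3), without those clusters (0.05, 78.1) and in cells with few cycle UMIs only (−0.000879, 58.4). The IL-7 and STAT5 list (0.20, percentile 95.8), receptor and adhesion genes (0.20, 95.4) and oxidative phosphorylation genes (−0.05, 39.5) lay within the middle 95% of random lists. The first came above that range with equal weight per cell (0.32, percentile 99.2), without those clusters (0.28, 99.2) and in cells with few cycle UMIs only (0.35, 99.7), and the second in 4 alternatives (0.24 to 0.29, percentiles 97.9 to 98.4). The median of the B cell surface list was 4.57 with the dendritic-like and innate-like clusters left out and 4.73 over members with 50 or more UMIs.

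**Figure D1:**
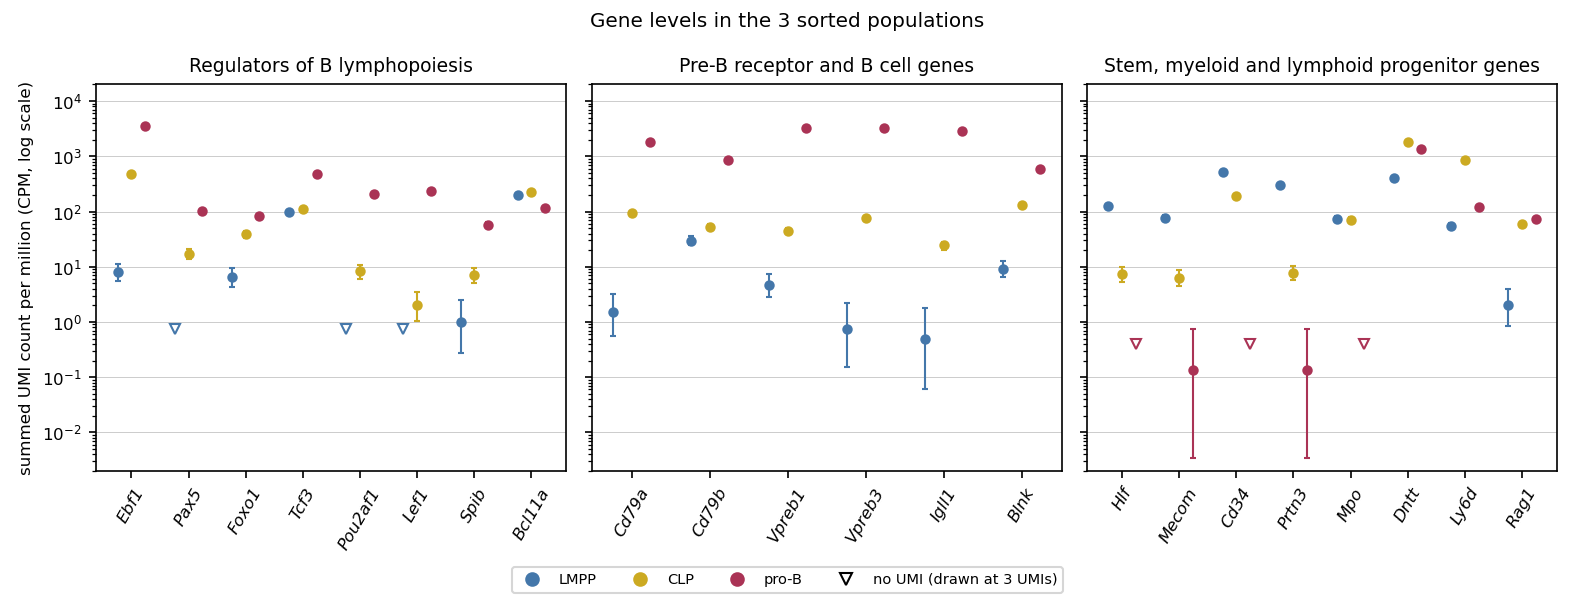
Summed UMI counts (CPM, log axis) of 22 genes in the LMPP, CLP and pro-B libraries, with bars for the 95% counting interval and open triangles for genes without a UMI, drawn at 3 UMIs. Ebf1 stood at 7.97, 472 and 3567 CPM, whereas Hlf and Prtn3 stood highest in LMPP, Ly6d in CLP, and Mpo at similar levels in LMPP and CLP.

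The comparison of pro-B cells with CLP asks which genes accompany entry into the B220+ stage. Genes of the surrogate light chain were among the most abundant named genes in pro-B, while most stem, myeloid and T or innate lymphoid genes were lower. Of these Ifitm3 still stood at 93.5 CPM, Spi1 at 46.4, Lmo2 at 38.3 and Lck at 29.0 CPM in pro-B, and Lyz2 stood at 82.3 CPM against 76.6 in CLP. Igll1, which encodes the lambda5 chain, was 120-fold higher (2909 against 24.3 CPM, log2 6.90, 6.67 to 7.15), and Vpreb1 75.8-fold higher (3316 against 43.7 CPM, log2 6.24, 6.07 to 6.43). Lef1, a transcription factor of the Wnt pathway, was 118-fold higher (237 against 2.01 CPM, log2 6.88, 6.07 to 7.84). Cd34 had 191 CPM in CLP and no UMI in pro-B, at least 469-fold lower, and Cox6a2, a cytochrome oxidase subunit gene, was 501-fold lower (0.95 against 476 CPM, log2 −8.97, −10.28 to −7.92). Of 3002 genes with 50 CPM or more in either library, 182 were at least 4-fold higher and 118 at least 4-fold lower in pro-B, so that 60.7% of these were higher, and 69.3% of the 3002 lay within 2-fold. Scaled to the total without mitochondrial and ribosomal genes, the counts were 180 higher and 251 lower, so that 41.8% were higher.

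The genes with the highest ratios in pro-B also included Slamf7 (104 CPM against 2 UMIs in CLP, log2 8.28, 6.42 to 11.33), Cplx2 (log2 8.08, 6.86 to 9.71), Sit1 (log2 7.62, 5.76 to 10.67), Rsph1 (78.7-fold) and Cdc25b, a phosphatase gene of the cell cycle (104-fold, log2 6.70, 5.77 to 7.83). Smtnl2 and Ttll11 had no UMI in CLP and were at least 178-fold and at least 101-fold higher. The genes with the lowest ratios included the chemokine genes Ccl4 (223-fold lower) and Ccl3 (at least 208-fold), Mpo (at least 175-fold), Mn1 (at least 149-fold), Tns1 (126-fold) and, with 1 to 3 UMIs in pro-B, Smim5 (log2 −8.72, −14.03 to −6.23), Dyrk4 (log2 −7.78, −10.84 to −5.92) and Mpeg1 (log2 −7.54, −9.82 to −5.98).

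Both B lineage lists lay above every random list. Of 12 regulators of B lymphopoiesis 10 were at least 2-fold higher in pro-B than in CLP (median 2.35, 2.20 to 2.496), with Ebf1 7.56-fold, Pax5 5.99-fold, Tcf3 4.33-fold, Pou2af1 25.7-fold, Spib 8.22-fold, Irf4 8.20-fold, Foxo1 2.19-fold and Ets1 2.22-fold higher. Bcl11a was 1.92-fold lower, and Ikzf3 stood at 2.71 CPM against 4.36 (log2 −0.68, −1.60 to 0.21). Since 24 of the 26 Ikzf3 UMIs in CLP lay in the 13 NK/innate lymphoid-like cells, its direction turned without the dendritic-like and innate-like clusters (log2 3.89, 1.245 to 9.26, from 1 UMI in CLP). Spib was 26.3-fold higher without them. Of 12 B cell surface and pre-B receptor genes 11 were at least 2-fold higher (median 4.16, 4.05 to 4.27), including Vpreb3 (43.7-fold), Cd79a (20.1-fold) and Blnk (4.34-fold). Id3, an inhibitor of E proteins, was 63.1-fold higher (264 against 4.19 CPM) while Id2 was 7.46-fold lower. The E and Id protein list as a whole had a median of 1.10 (0.19 to 1.21, percentile 98.7), which was 0.08 (percentile 30.6) over members with 50 or more UMIs.

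Genes of other lineages were lower in pro-B. Stem and multipotent genes had 12 of 13 measured members at least 2-fold lower (median −3.61, −3.97 to −3.12), with Hlf at least 18.1-fold and Ifitm1 16.2-fold lower, and myeloid genes had 8 of 10 (median −3.69, −4.11 to −2.82). T and innate lymphoid genes had 10 of 12 lower (median −4.13, −4.49 to −3.62), with Tox 49.6-fold, Nkg7 30.6-fold, Gata3 24.2-fold and Lck 4.72-fold lower. Early lymphoid genes were lower in 7 of 11 (median −1.75, −2.02 to −1.49), with Ly6d 7.25-fold, Notch1 7.24-fold and Satb1 5.55-fold lower, while Dntt was 1.33-fold lower and Rag1 stood at 73.0 against 58.8 CPM. All 4 of these lists lay below every random list. Dendritic cell genes were lower in 4 of 5 (median −1.59, percentile 0.22), with Siglech at least 123-fold and Irf8 3.01-fold lower. MHC class II genes were lower in 5 of 6 (median −1.92, percentile 0.11), with H2-DMa 11.1-fold and Cd74 7.76-fold lower, whereas H2-Ab1 was 3.71-fold higher. Markers of dendritic-like and innate-like cells in the CLP library enter these ratios: without those clusters the T and innate lymphoid median was −2.57 and the dendritic median −0.997, and Gata3 was 5.94-fold, Id2 4.84-fold, Irf8 1.86-fold, Ly6d 4.60-fold and Siglech at least 47.7-fold lower.

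Cell division genes were higher in pro-B than in CLP. All 18 G2/M genes were at least 4-fold higher (median 3.84, 3.56 to 3.98), with Ube2c 56.1-fold, Birc5 15.9-fold, Cenpa 7.34-fold and Top2a 6.51-fold higher, and 11 of 18 S phase genes were at least 2-fold higher (median 1.40, 1.28 to 1.501), with Rrm2 14.1-fold and Pcna 3.96-fold higher. Both medians lay above every random list. Without the dendritic-like and innate-like clusters Birc5 was 27.5-fold, Rrm2 24.0-fold and Top2a 9.99-fold higher. The dendritic-like CLP cells left out were rich in cycle transcripts, with 83.6% of 61 thinned cells over the S phase and 31.1% over the G2/M threshold. These folds thus rise through the choice of cells. Within the IL-7 and STAT5 list 8 of 13 members were at least 2-fold lower (median −1.34, −1.64 to −1.22, below every random list). Bcl2, which protects from cell death, was 16.5-fold lower and Ccnd2 3.56-fold lower, while Ccnd3, another D-type cyclin, was 3.20-fold higher. Hmgb2 (7.22-fold) and Hmgb1 (3.65-fold), members of the V(D)J recombination list, were higher, but the list median of 0.34 lay at percentile 85.0 (0.76, percentile 99.2, with equal weight per cell). Immediate early genes were lower in 9 of 13 (median −1.45, −1.89 to −1.31, below every random list), with Fos 9.23-fold and Junb 6.52-fold lower. Receptor and adhesion genes had a median of −0.99 (percentile 0.02), with Cd27 8.16-fold lower. Oxidative phosphorylation genes had a median of 0.88 (percentile 98.2), with Atp5b 2.07-fold and Ndufa4 1.94-fold higher, which came inside the middle 95% with equal weight per cell (0.78, percentile 95.3), without the deepest 5% of cells (0.86, 96.9) and in cells with few cycle UMIs only (0.64, 93.02). Glycolysis genes (0.69, percentile 96.4, and 0.80, 98.02, without pro-B cluster 1), interferon stimulated genes (−0.55, 15.2) and Notch targets (0.03, 41.3) lay within the middle 95% of random lists with all cells. The notch list held Notch1 on the lower side and Nrarp (2.38-fold) and Hes1 (1.79-fold) on the higher side.

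Part of this comparison moved with the choice of cells. In an alternative chosen after the data were seen, with only the 613 CLP and 324 pro-B cells that had fewer than 3 S phase and fewer than 3 G2/M UMIs after thinning, 92 of the 182 higher and 94 of the 118 lower genes remained, the stem, myeloid and T or innate lymphoid medians were −2.01, −1.25 and −2.04, and that of B cell surface genes was 5.34. In the same cells the median was 2.28 for G2/M, −0.49 for S phase, −1.16 for early lymphoid, −0.75 for IL-7 and STAT5, −0.86 for dendritic, −0.90 for MHC class II and 0.23 for interferon stimulated genes. Calls changed for Notch (−1.87, percentile 0.51) and V(D)J recombination genes (1.01, 99.8), which came outside the middle 95% of random lists, for E and Id protein genes (0.22, 41.3), which came inside it, and for S phase genes, which came below it (percentile 0.97). With fewer cells the floor of 3 UMIs is a higher CPM, so bounds for genes with no UMI in pro-B shrink by construction. How much this moved the stem, myeloid and T or innate lymphoid medians was not tested. Most of the 324 pro-B cells came from the shallow pro-B cluster 1 (median 2803.5 UMIs). Only 9.78% and 15.9% of its 358 thinned cells reached 3 UMIs of the G2/M and S phase lists. The myeloid median also moved to −1.22 over members with 50 or more UMIs and to −4.82 with cells of very high Actb left out, that of immediate early genes to −2.38 over members with 50 or more UMIs, and that of interferon stimulated genes to −1.21 without pro-B cluster 1, where it lay below the middle 95% (percentile 1.27).

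**Figure D2:**
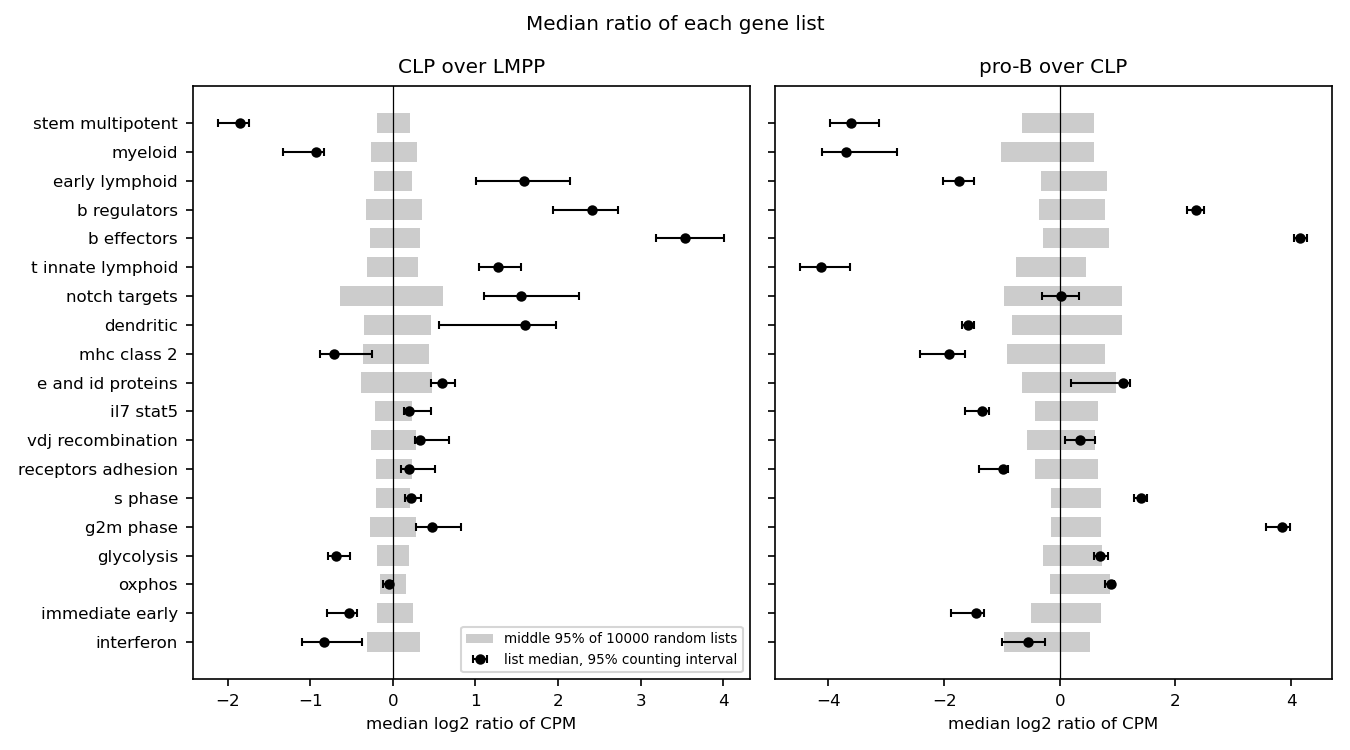
Median log2 ratio of CPM (x axis) of 19 gene lists (y axis) for CLP over LMPP and for pro-B over CLP, with points and bars for the median and its 95% counting interval and grey bands for the middle 95% of 10000 random lists matched on expression. B effector genes, at 3.54 and 4.16, had the highest medians in both comparisons, while T and innate lymphoid genes stood at 1.28 and then at −4.13.

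From LMPP to pro-B, 233 genes were at least 4-fold higher and 122 at least 4-fold lower among 2995 with 50 CPM or more in either library, so that 65.6% were higher (42.8% when scaled to the total without mitochondrial and ribosomal genes). All 12 B cell surface and pre-B receptor genes were at least 2-fold higher (median 7.52, 7.13 to 7.58) and 11 of 12 B regulators were (median 4.22, 3.72 to 5.00). The stem and multipotent median was −5.49 (−5.88 to −5.21) and the myeloid median −5.38 (−5.55 to −4.30), while early lymphoid genes had a median of 0.12 (−0.14 to 0.35, percentile 45.1). With only cells of few cycle UMIs the stem median was −3.71, the myeloid median −2.95 and that of B regulators 5.18. The floor is a higher CPM with these fewer cells, which shrinks the bounds for genes with no UMI in pro-B. Taking the 2 steps in turn, 9 genes were at least 4-fold higher at both, including Ebf1, Cd79a, Vpreb3, Vpreb2, Blnk, Mzb1 and Arl5c. Another 12 genes were at least 4-fold higher in CLP than in LMPP and at least 4-fold lower in pro-B than in CLP, including Ly6d, Cox6a2, Mpeg1 and Dyrk4. Ifitm1 and Ctla2a were at least 4-fold lower at both steps, and 0 genes were lower and then higher; Ctla2a was singled out after its values were seen.

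Shares of cells with a UMI were compared after thinning every cell to 2000 UMIs, which left 573 LMPP, 908 CLP and 1070 pro-B cells. Ebf1 was found in 0.52% (interval 0.11 to 1.52) of LMPP, 41.4% (38.2 to 44.7) of CLP and 98.3% (97.4 to 99) of pro-B cells. Without thinning the shares were 1.04%, 57.0% and 99.8%. Free RNA comes from the cells of its own library, so the background was read within CLP. In its plasmacytoid dendritic-like cluster (median 7468 UMIs, against 6258.5 in the whole library) Ebf1 was found in 4.92% (1.03 to 13.7) of 61 thinned cells and Cd79a in 0 (0 to 5.87). Pax5 was found in 0 of 573 LMPP, 4.30% (3.07 to 5.83) of CLP and 19.0% (16.7 to 21.5) of pro-B cells (unthinned 0, 8.33% and 43.9%), and Cd79a in 0.17%, 12.004% and 95.5% (unthinned 0.35%, 21.9% and 99.8%). Vpreb1 was found in 0.70%, 5.29% and 98.8% and Igll1 in 0.17%, 2.09% and 98.7% (unthinned 3.28%, 11.4% and 99.9%, and 0.35%, 3.69% and 99.9%). Rag1 was found in 0.35% of LMPP, 10.1% of CLP and 17.4% of pro-B cells (unthinned 0.86%, 23.6% and 34.3%). The 32 Ebf1 UMIs of LMPP were held almost wholly by a few cells, with 96.9% of them in the 5 cells that had most.

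Dntt was found in 40.1% of LMPP, 92.0% of CLP and 85.0% of pro-B cells (unthinned 64.9%, 96.9% and 96.8%), and Ly6d in 2.62%, 46.6% and 16.4% (unthinned 5.18%, 67.0% and 31.6%). Mpo was found in 9.95% (7.62 to 12.7) of LMPP and 12.3% (10.3 to 14.7) of CLP cells and in 0 of 1070 pro-B cells, which allows a share of up to 0.34% of cells with a UMI at this depth and does not limit the cells that express it (unthinned 29.7%, 29.3% and 0). In the plasmacytoid dendritic-like cluster of CLP Mpo was found in 0 of 61 thinned cells (0 to 5.87%), while for LMPP the part that free RNA adds stays open. Cebpa was found in 7.68% of LMPP, 0.77% of CLP and 0.09% of pro-B cells (unthinned 21.2%, 3.69% and 0.18%). Gata3 was found in 0.52%, 1.76% and 0.09% of cells (unthinned 3.7997%, 2.95% and 0.18%), with 58.2% of its CLP UMIs in 5 cells, and Notch1 in 17.8%, 28.3% and 4.58% (unthinned 41.6%, 55.4% and 13.0%).

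**Figure D3:**
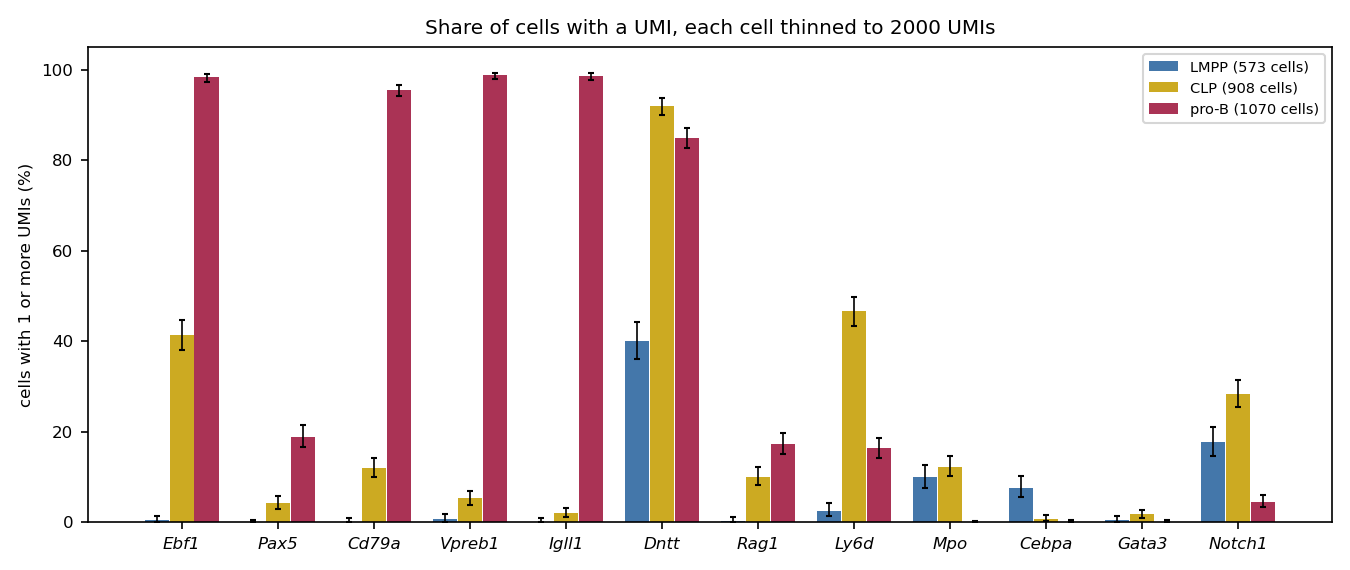
Share of cells (y axis, percent) with 1 or more UMIs of 12 genes (x axis) in LMPP (573 cells), CLP (908 cells) and pro-B (1070 cells), each cell thinned to 2000 UMIs, with 95% Clopper-Pearson intervals. The Ebf1 bars stand at 0.52%, 41.4% and 98.3%, and Mpo is found in LMPP and CLP but in no pro-B cell.

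Within CLP, the B lineage genes were found together more often than their single shares would give. Ebf1 and Pax5 were both found in 3.96% (2.79 to 5.45) of thinned CLP cells, against a product of the single shares of 1.78%. Pax5 was found in 9.57% (6.80 to 13.0) of CLP cells with Ebf1 and in 0.56% (0.12 to 1.64) of those without, and Cd79a in 24.7% (20.5 to 29.4) and 3.01% (1.73 to 4.84). Ly6d was found in 57.7% (52.5 to 62.8) of CLP cells with Ebf1 and in 38.7% (34.6 to 43.0) of those without. A myeloid list gene and an early lymphoid gene were both found in 57.1% of LMPP cells (product 57.5%), 44.5% of CLP (44.3%) and 27.5% of pro-B cells (26.2%). In CLP 98.7% of cells held an early lymphoid gene, so that this value could hardly leave the product. In pro-B an early lymphoid gene was found in 96.7% (94.03 to 98.4) of cells with a myeloid gene and in 90.3% (88.02 to 92.3) of those without. In CLP a myeloid gene was found with Ebf1 or Pax5 in 19.2% of cells (product 18.8%). Narrower pairs, chosen after the data were seen, lay below the product in LMPP, where Dntt was found with Prtn3 or Mpo in 14.8% of cells (product 18.98%) and with Hlf or Mecom in 9.25% (product 13.1%). These shares are not corrected for depth within the thinned cells or for free RNA, and in pro-B cells, where Prtn3, Mpo and Cebpa were nearly absent, 28.4% still held a UMI of the myeloid list.

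Transcripts of the cell cycle were more common in pro-B cells. After thinning, 3 or more UMIs of the G2/M list were found in 3.49% (2.14 to 5.34) of LMPP, 5.95% (4.50 to 7.69) of CLP and 52.1% (49.1 to 55.2) of pro-B cells, and without thinning in 10.7%, 13.3% and 67.1%. For the S phase list the shares were 23.9% (20.5 to 27.6), 29.96% (27.0 to 33.1) and 58.2% (55.2 to 61.2), and without thinning 64.4%, 64.2% and 71.8%. These are shares over a count threshold and not calls of dividing cells. The part that free RNA adds to them stays open.

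Each library was also clustered on its own to describe the cells it holds. In CLP, clusters 2 and 4, with 262 and 67 cells, were called early B-like from their markers, cluster 5 (61 cells) plasmacytoid dendritic-like and cluster 6 (13 cells) NK/innate lymphoid-like. Genes of division such as Ccnb2 and Ube2c led cluster 4 beside Igll1. The name is weaker for cluster 4, where early B markers had a median log2 ratio of 1.05 over other CLP cells, against 1.61 in cluster 2. Clusters 1 and 3, with 309 and 236 cells, kept no name. Ccl5, Wfdc17 and Cd34 were among the leading genes of cluster 1, and Abhd2, Notch2 and Actb among those of cluster 3, whose median cell held 3153 UMIs. In LMPP, 186 cells formed an HSC/multipotent-like cluster, 65 an early lymphoid-like and 21 a plasmacytoid dendritic-like one. The other LMPP clusters kept no name and were led by S phase genes such as E2f1 and Uhrf1 (161 cells), by Dqx1 and Ccl5 (91), by mitotic genes such as Ccnb2 (42) and by interferon stimulated genes such as Ifit3 (13). All 6 pro-B clusters stayed unnamed, the largest with 394 cells and a median of 2803.5 UMIs. Cluster sizes were not compared between libraries, and the leading genes define the clusters and are not results.

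**Figure D4:**
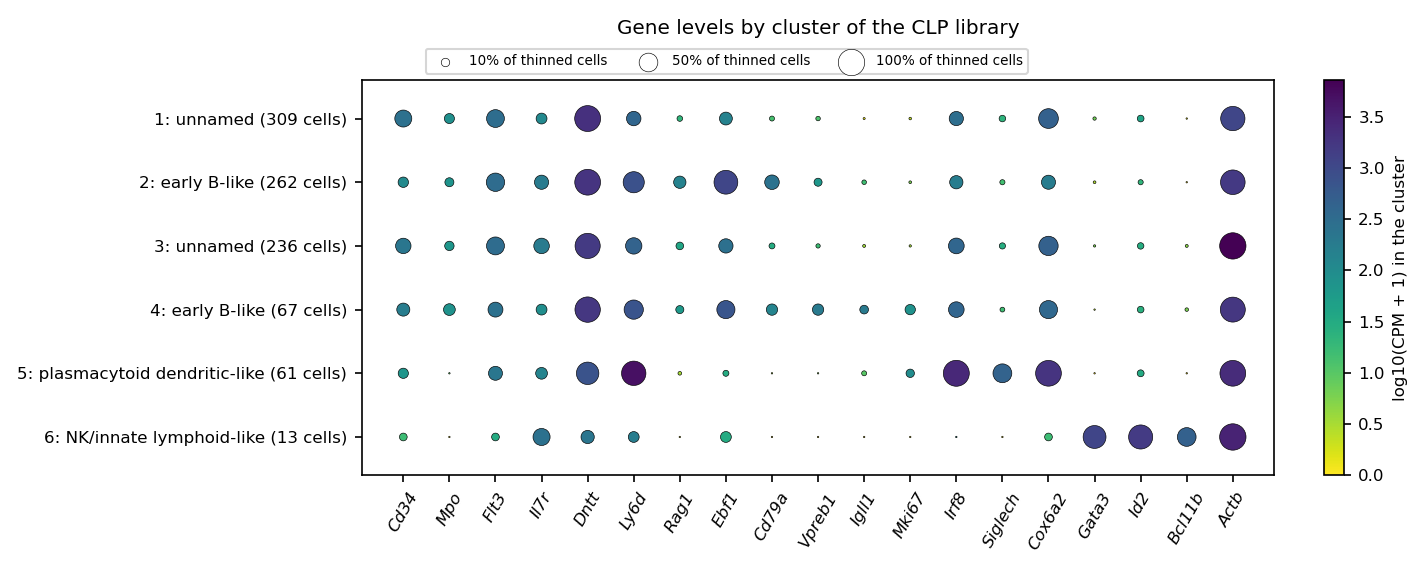
Level of 19 genes (x axis) in the 6 clusters of the CLP library (y axis), with dot area for the share of thinned cells with a UMI and colour for log10 of CPM plus 1. Dots for Ebf1 and Cd79a are darkest in cluster 2, for Irf8, Siglech and Cox6a2 in cluster 5, for Gata3, Id2 and Bcl11b in cluster 6 and for Actb in cluster 3.

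Markers of other cell types were summed in each library as a description of what the gates held. The HSC/multipotent markers summed to 483, 91.8 and 9.77 CPM in LMPP, CLP and pro-B, those of neutrophil and monocyte progenitors to 423, 90.5 and 0.54, early lymphoid markers to 703, 2426 and 1594, and early B markers to 54.3, 919 and 16726. Plasmacytoid dendritic markers summed to 601, 1506 and 364 CPM, NK and innate lymphoid markers to 206, 338 and 25.8, plasma cell markers to 80.2, 241 and 1373 (of which Mzb1 gave 1313 in pro-B), and erythroid markers to 497, 48.4 and 194 (of which Car2 gave 444, 43.6 and 165). T cell markers summed to 70.5, 98.9 and 48.6 CPM, conventional dendritic markers to 151, 99.7 and 134, and those of monocytes and macrophages to 186, 102 and 84.2. Those of late pre-B or mature B cells summed to 114, 63.3 and 18.3 CPM from the 7 of 9 markers used here. The lowest sums in LMPP and CLP were those of megakaryocytes (22.7, 4.36 and 1.36), mast cells and basophils (9.47, 17.6 and 1.22), mature neutrophils (9.22, 0.84 and 0.27) and stroma (1.99, 8.04 and 3.801).

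The genes named most often lie at the following positions of GRCm38, all annotated as protein coding. Ebf1 (ENSMUSG00000057098) spans chromosome 11 from 44617317 to 45008091 on the plus strand, and Pax5 (ENSMUSG00000014030) chromosome 4 from 44524757 to 44710487 on the minus strand. Igll1 and Vpreb1 lie close together on the minus strand of chromosome 16, from 16860671 to 16863985 and from 16868403 to 16870843. Cd79a lies on chromosome 7 from 24897381 to 24902197 (plus strand), Dntt on chromosome 19 from 41029275 to 41059525 (plus) and Ly6d on chromosome 15 from 74762056 to 74763620 (minus). Mpo lies on chromosome 11 from 87793581 to 87804413 (plus), Prtn3 on chromosome 10 from 79874476 to 79883174 (plus) and Hlf on chromosome 11 from 90336536 to 90390895 (minus).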

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

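The alternatives without cells of very high Actb, without the dendritic-like and innate-like clusters, with few cycle UMIs only and without pro-B cluster 1 were chosen after the data were seen. Leaving out replicates was not possible with 1 library per group. No paired analysis was possible because each group had 1 library and no test was made. Of 84 gene counts under alternatives 65 stayed within 1.5 times. Scaled to the total without mitochondrial and ribosomal genes, the genes at least 4-fold lower numbered 40 for CLP over LMPP, 251 for pro-B over CLP and 305 for pro-B over LMPP. This follows from construction: CPM rises in every library, most in those rich in ribosomal UMIs. At 20 CPM there were 60 higher and 48 lower genes for CLP over LMPP, and 244 and 302 lower for pro-B over CLP and over LMPP. At 100 CPM there were 21 and 11, 119 and 61, and 143 and 57 higher and lower genes in the 3 comparisons. At 2-fold there were 121 and 70, 625 and 296, and 645 and 303. With all cells and other weights, scalings and filters at 50 CPM, at least 34 of the 35 higher and all 23 lower genes of CLP over LMPP were kept in each alternative. The other comparisons kept fewer. Scaled to the total without mitochondrial and ribosomal genes, 151 of 182 higher genes of pro-B over CLP and 195 of 233 of pro-B over LMPP were kept. With equal weight per cell, 108 of 118 and 110 of 122 lower genes were kept. For the stem, myeloid and both B lineage lists, all 112 medians of the first 2 comparisons kept their sign, and 94 lay within counting error. B effector genes for CLP over LMPP moved to 4.57 without the dendritic-like and innate-like clusters and to 4.73 over members with 50 or more UMIs. For pro-B over CLP, B regulators stood at 2.04 and B effectors at 3.85 with the total without mitochondrial and ribosomal genes. B effectors stood at 4.40 with equal weight per cell, 4.28 without the deepest 5% of cells, 4.47 without the dendritic-like and innate-like clusters and 3.93 without pro-B cluster 1. B regulators stood at 2.53 without cells of very high Actb, 2.63 without those clusters and 2.58 over members with 50 or more UMIs. The myeloid median was −4.82, −4.52 and −1.22 in the same 3 alternatives. With few cycle UMIs only, the medians for pro-B over CLP were −2.01 (stem), −1.25 (myeloid), 2.71 (B regulators) and 5.34 (B effectors). The stem and myeloid lists have members at the floor in pro-B, and the floor is a higher CPM with fewer cells. Over all 48 list medians outside the middle 95% of random lists, 667 of 672 values kept their sign and 19 came inside that range, while of 168 values of the 12 list medians inside it 14 came outside. The other 5 all arose with few cycle UMIs only, a choice of cells that removes cycle transcripts by construction: S phase genes at −0.000879, −0.49 and −0.50 for CLP over LMPP, pro-B over CLP and pro-B over LMPP, G2/M genes at −0.11 for CLP over LMPP, and receptor and adhesion genes at 0.053 for pro-B over LMPP. Gata3 (log2 −0.75) and Bst2 (log2 −0.15) changed sign for CLP over LMPP without the dendritic-like and innate-like clusters, the first since 76 of its 98 UMIs in CLP lay in them. Other named genes that changed sign, all with intervals that held 0 at first, were Pcna (log2 −0.14), Mpo (0.05) and Cox6c (−0.02) for CLP over LMPP and Ikzf3 (3.89) and Lyz2 (−0.00616) for pro-B over CLP. For Bst2, for receptor and adhesion genes and for the moved medians of other lists, the cause was not tested. The share of cells with Ebf1 was 57.0% in CLP and 99.8% in pro-B without thinning, 28.8% and 94.8% at 1000 UMIs, and 25.2% and 96.1% at 2 or more UMIs. The share over the G2/M threshold was 10.7%, 13.3% and 67.1% in LMPP, CLP and pro-B without thinning, 6.81%, 7.71% and 66.5% at 2 or more UMIs, and 2.09%, 3.63% and 39.8% at 5 or more. In LMPP the Ebf1 share was 1.04% without thinning, 0.86% at 1000 UMIs and 0.35% at 2 or more UMIs, against 0.52%. Depth sets the shares of CLP and pro-B, since fewer UMIs per cell or a higher threshold lowered each of these. Among cluster results 20 of 36 stayed alike. The plasmacytoid dendritic-like cluster of LMPP was not found at resolution 0.3, with 10 principal components or without cycle genes, and that of CLP not at 0.3, while it held 6.43% to 10.3% of CLP otherwise. The early lymphoid-like cluster of LMPP was not found at 0.3 and held 11.1% to 21.2% of LMPP otherwise, HSC/multipotent-like clusters held 17.4% to 48.9% of LMPP, and early B-like clusters 23.3% to 34.7% of CLP.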

Other observations

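The pairs of genes in the next paragraph and their values without a cluster, all tests on Mpo and on dendritic cell genes, and the test of mitochondrial and Malat1 shares in cells of very high Actb were chosen only after the result was seen. The other 2 tests on those cells were set before their results were seen.

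Some pairs of genes of different fates divided the cells of a library. In LMPP, Dntt was found in 31.4% (interval 25.9 to 37.3) of thinned cells with Prtn3 or Mpo and in 48.0% (42.3 to 53.8) of those without, and in 28.3% (22.01 to 35.4) of cells with the stem cell genes Hlf or Mecom and 45.9% (40.8 to 51.0) of those without. In CLP the first pair went the other way, with Dntt in 97.6% (93.04 to 99.5) of cells with Prtn3 or Mpo and in 91.1% (88.9 to 92.98) of those without, and for Hlf or Mecom the intervals overlapped (82.6%, 61.2 to 95.05, and 92.2%, 90.2 to 93.9). For the first pair the intervals barely part, Dntt was found in most CLP cells (92.0%), and no cluster was left out. That pair also rests on different genes in LMPP and CLP. Prtn3 was found in 238 and Mpo in 57 thinned LMPP cells, against 12 and 112 thinned CLP cells. The change of direction thus sets mainly Prtn3 in LMPP against mainly Mpo in CLP. Ebf1 in CLP was found in 31.9% (27.7 to 36.4) of cells with Siglech or Cox6a2 and in 51.2% (46.5 to 56.0) of those without. Of the 461 cells with either gene 444 held Cox6a2 and 71 held Siglech, so this split is largely that of Cox6a2. Cd34 divided CLP in the same way, with Ebf1 in 27.5% (22.2 to 33.3) of cells with Cd34 and in 47.1% (43.2 to 51.0) of those without. Ebf1 was also found in 34.4% (29.1 to 40.01) of CLP cells with Irf8 and in 45% (40.97 to 49.1) of those without, and in pro-B, where 296 cells held Irf8, the shares were 97.97% (95.6 to 99.3) and 98.4% (97.3 to 99.2). Of the 61 plasmacytoid dendritic-like CLP cells 59 held Irf8, and without that cluster the shares for Irf8 in CLP were 41.4% (35.2 to 47.8) and 45.2% (41.1 to 49.2), which overlap, against 35.9% (31.2 to 40.8) and 51.3% (46.6 to 56.1) for Siglech or Cox6a2 and 28.5% (22.98 to 34.4) and 50.7% (46.6 to 54.8) for Cd34. The other pairs could not be judged in pro-B, where Prtn3, Mpo, Hlf, Mecom and Cd34 were found in 0 of 1070 thinned cells and Siglech or Cox6a2 in 3.

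Cells in which Actb, the gene of cytoplasmic actin, took 4000 CPM or more made up 32.9% of CLP (312 cells), 10.7% of LMPP (62) and 2.89% of pro-B (32), and their median depth was lower than that of other cells (3098.5 against 7487 UMIs in CLP, 3107 against 7139 in LMPP). Low depth by itself is argued against, since only 0.641% (0.175 to 1.63) of 624 other CLP cells became such cells when they were thinned to the same depth. A state of CLP alone is argued against by LMPP, where the 19 genes other than Actb that lead CLP cluster 3, such as Abhd2, Notch2 and Rbm15, had a median log2 ratio of 1.89 (1.53 to 2.20) between these and other cells, with 19 of 19 above 0. In the 32 such pro-B cells the median was 0.83 (0.25 to 1.14), with 13 of 18 measured genes above 0, and such cells were found in every cluster of CLP (4.21% to 91.9%) and of LMPP (5.38% to 16.5%). Leakage from damaged cells stays open, since the ratio of mitochondrial shares to other cells was only 1.08 in CLP and 1.07 in LMPP while that of Malat1, a nuclear RNA, was 1.36 and 1.15, and a reaction that differed between droplets and a cell state that the libraries share were not tested.

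Mpo stood at similar levels in CLP and LMPP although 5 of 10 measured myeloid genes were at least 2-fold lower in CLP. LMPP-type cells in the CLP sort would bring Prtn3 as well, but CLP held 0.108 Prtn3 UMIs per Mpo UMI (0.0779 to 0.147) against 4.04 in LMPP. Free RNA would reach all droplets, but Mpo in the plasmacytoid dendritic-like cluster was 0.118 of its level in other CLP cells (0.0321 to 0.305, from 4 UMIs). A separate myeloid cell type that lacks Dntt is argued against by Dntt, found in 98.2% (93.7 to 99.8) of thinned CLP cells with Mpo, 91.1% of those without and 25% (5.49 to 57.2) of the 12 NK/innate lymphoid-like ones, taken as background, with means of 3.91, 3.56 and 0.667 UMIs. A myeloid-leaning part of CLP that holds Dntt stays open. In the unnamed CLP cluster 1 (309 cells), 3 measured neutrophil and monocyte progenitor markers had a median log2 ratio of 1.67 over other CLP cells. The 3 were Mpo itself, Prtn3 (46 UMIs in CLP) and Cebpa (41 UMIs). The value thus in part restates where Mpo lies and otherwise rests on few UMIs. None of these markers was among its 10 leading genes. That CLP themselves may carry Mpo transcripts with little Prtn3 is a hypothesis found on these same data.

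Ly6d, Irf8, Cox6a2, Siglech and Mpeg1, genes also known from plasmacytoid dendritic cells or macrophages, were higher in CLP than in LMPP. Irf8, Cox6a2 and Siglech were taken from 8 plasmacytoid dendritic markers because they were at least 2-fold higher in CLP. Markers that rose less, such as Bst2 (log2 0.14), were left out, and Ly6d and Mpeg1 were added. The values below thus hold for these 5 genes and not for dendritic cell genes as a whole. The plasmacytoid dendritic-like cluster of 61 CLP cells, as found with the main settings, does not alone account for the rise of these 5 genes. With it left out of CLP alone, and all LMPP cells kept, the median log2 ratio of the 5 genes was 2.26 (1.86 to 2.68). With other clustering settings that class held up to 10.3% of CLP, and leaving out that larger set was not run. The cluster of 61 cells did carry part of the difference, as Ly6d, also known from B-biased CLP, went from 4.01 to 3.34 (3.14 to 3.54), Irf8 from 1.88 to 1.18 (1.03 to 1.33) and Siglech from 2.79 to 1.41 (0.81 to 2.06). Free RNA from those cells would keep their genes in 1 ratio, but other CLP cells held 19.0 Cox6a2 UMIs per Siglech UMI (15.6 to 23.3) against 4.31 in the cluster. This argues against free RNA as the only source of Cox6a2 there, and for Siglech, Irf8, Ly6d and Mpeg1 free RNA stays open. Siglech is also among the genes that lead the cluster, which may lower the ratio there. The sorted population itself, with part of this program in CLP outside the dendritic-like cluster, stays as a candidate explanation and a hypothesis.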
